A study of Mus musculus with 6 samples.

How the data were processed

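Resident peritoneal macrophages were recovered by lavage from 7-week-old mice, pooled from 2 to 3 animals per sample and sorted, per the labels' protocols, as cells high in CD11b and low or negative for MHC class II. The material was total RNA of 3 pools from mice with a conditional deletion of Gata6 (Gata6-KO) and 3 pools from wild type mice (Gata6-WT). The label was biotin, and each pool was measured on 1 array. The labels call the pools biological replicates and the series design calls the mice sex-matched; the sex of each pool, the Cre line and the deleted part of the gene are not given in the sources used here.

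The deposited values are linear intensities, 1 probe set signal per probe set and array, for 45101 probe sets. Per the submitters' processing notes the tools were MAS5 and affy, with no version given. In the values, the mean without the highest and lowest 2% of probe sets was 500 on each of the 6 arrays, so the authors' intensity scale was set to a common trimmed mean before deposit. MAS5 subtracts a stray signal based on mismatch probes within each array, which leaves low signals noisy, and no detection calls were used here. The precision of each comparison is limited by the number of arrays. No pair of arrays held identical values.

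Gene symbols came from the array annotation table: 34958 probe sets had 1 symbol, 932 had several and 9211 had none here. Probe sets with several symbols were tested but not named. Of the probe sets with 1 symbol, 34754 matched a gene identifier of the GRCm38.p6 gene table, and 0 symbols needed an update. No genome build is named for the values, so no coordinates are given.

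Signals were converted to log2(signal + 16) with no further normalization. The 64 control probe sets were left out, and a probe set was tested if its mean log2 value over all 6 arrays was above the 40th percentile (5.99, a signal of 47.5), which left 27022. Differences between Gata6-KO and Gata6-WT were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. Fold changes are on the log2(signal + 16) scale and understate the change of low signals. For single-gene and gene list results each gene was represented by its tested probe set with the highest mean, giving 12511 genes. Of 477 listed or named genes 209 had several tested probe sets, and 0 had probe sets past the threshold in opposite directions.

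Gene lists were fixed from textbook knowledge before the data were examined, as were the tests, most of the variations of the fit and the rule for naming genes. The rule takes each Gata6 probe set, the 12 genes with the largest fold change in each direction that pass the threshold with non-overlapping groups, and from each list up to 4 members past the threshold with the largest change or, if none passes, up to 3 with the smallest p. Any other list member may be named with its value, and sex-linked genes and the 3' and 5' control probe sets of Actb and Gapdh are used as checks. The 34 lists hold 610 genes, of which 463 were measured, and the 30 lists with 5 or more measured genes were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run as alternatives. Single values were compared by an exact two-sided permutation test, whose smallest p with 3 against 3 arrays is 0.1.

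The limma and camera steps were tested on simulated arrays with the means and spreads of the 27022 probe sets. Of 50 probe sets each changed by a log2 value of 0.5, 1, 2 and 3, the fit recovered 2%, 32%, 66% and 80%; 4 of its 94 calls were false. Camera gave a p of 4.3e-45 for a simulated list of 25 probe sets shifted by log2 1 and 0.94 for an unshifted list of 25. Far fewer probe sets were changed in the simulation than the 2916 called in the data, so recovery in the data can differ. Simulated probe sets were also drawn independently, so the camera check says nothing about lists of correlated genes.

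The fit was varied with pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization and median scaling, a fit without the trend, array weights, the replicate number as a block, omission of each array, stricter thresholds (adjusted p under 0.01, a change of at least 2-fold, or limma's treat against 1.5-fold) and the mean of a gene's probe sets. A term for sex-linked expression and a fit of replicates 2 and 3 only were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.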

Results

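The series measured gene expression in resident macrophages of the peritoneal cavity from mice with a conditional deletion of Gata6, which encodes a transcription factor, and from wild type mice. It holds 3 Gata6-KO and 3 Gata6-WT arrays, each from a pool of 2 to 3 mice. Median signals lay between 79.7 and 88.5 per array. Arrays of 1 genotype correlated at r = 0.964 to 0.972 over tested probe sets and arrays of different genotype at 0.930 to 0.951, and the first principal component, with 46.5% of the variance, separated the genotypes. Xist, which is expressed from the inactive X chromosome, had a signal of 102 in Gata6-KO replicate 1 and 113 in Gata6-WT replicate 1 but 11158 to 13749 in the other 4 arrays, while the Y-linked gene Eif2s3y had 3494 and 3674 in the replicates numbered 1 and 1.20 to 15.3 elsewhere. The replicates numbered 1 therefore carried male-type and the others female-type expression in both genotypes, and values within each type are given below as female-type (2 arrays against 2) and male-type (1 against 1, no test). These values by type, the fit with a sex-linked term and the fit of the female-type arrays were chosen after the data were seen.

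The targeted gene was examined first. Of the 3 Gata6 probe sets, the one with the lowest signal fell from 423 ± 76.6 in Gata6-WT to 180 ± 6.47 in Gata6-KO (SD, n = 3; log2 -1.15 ± 0.19 SE, limma adjusted p = 0.0043). The probe set with the highest signal fell from 6372 ± 938 to 3497 ± 828 (log2 -0.88 ± 0.17, adjusted p = 0.011), and in both the 3 Gata6-KO arrays lay below all Gata6-WT arrays (exact permutation p = 0.1, the smallest possible). The intermediate probe set had 1758 ± 399 against 1775 ± 443 (log2 -0.01 ± 0.21, adjusted p = 0.98). The Gata6-KO arrays kept 40.8% to 43.5% of the wild type mean at the lowest-signal probe set. Replicates 1, 2 and 3 kept 69.9%, 47.7% and 47.05% at the highest-signal probe set and 121.7%, 76.8% and 98.6% at the intermediate one. The positions of these probe sets relative to the deleted part are not known here, and a probe set outside it checks nothing about the labels.

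Gata6-KO and Gata6-WT macrophages differed in many genes, with Mrc1, Folr2, Cd163 and Lyve1 among the largest rises and Hdc, Garnl3 and Ltbp1 among the largest falls. Of 27022 probe sets, 1384 were higher and 1532 lower in Gata6-KO, of which 553 and 703 changed at least 2-fold; 31.0% of probe sets had non-overlapping groups, where chance gives 10%. By gene, 702 of 12511 were higher and 933 lower. Which direction held more probe sets depended on scaling, with 1638 higher and 1256 lower after median scaling and 1481 and 1491 after quantile normalization. It also turned without Gata6-WT replicate 1 (1240 higher, 1236 lower), replicate 2 (954, 939) or replicate 3 (1121, 1116). The total of 2916 changed probe sets was 1886 without Gata6-KO replicate 2, 1856 without Gata6-KO replicate 3 and 1893 without Gata6-WT replicate 2. It was 2894 with a term for sex-linked expression and 1654 in the female-type arrays alone.

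**Figure D1:**
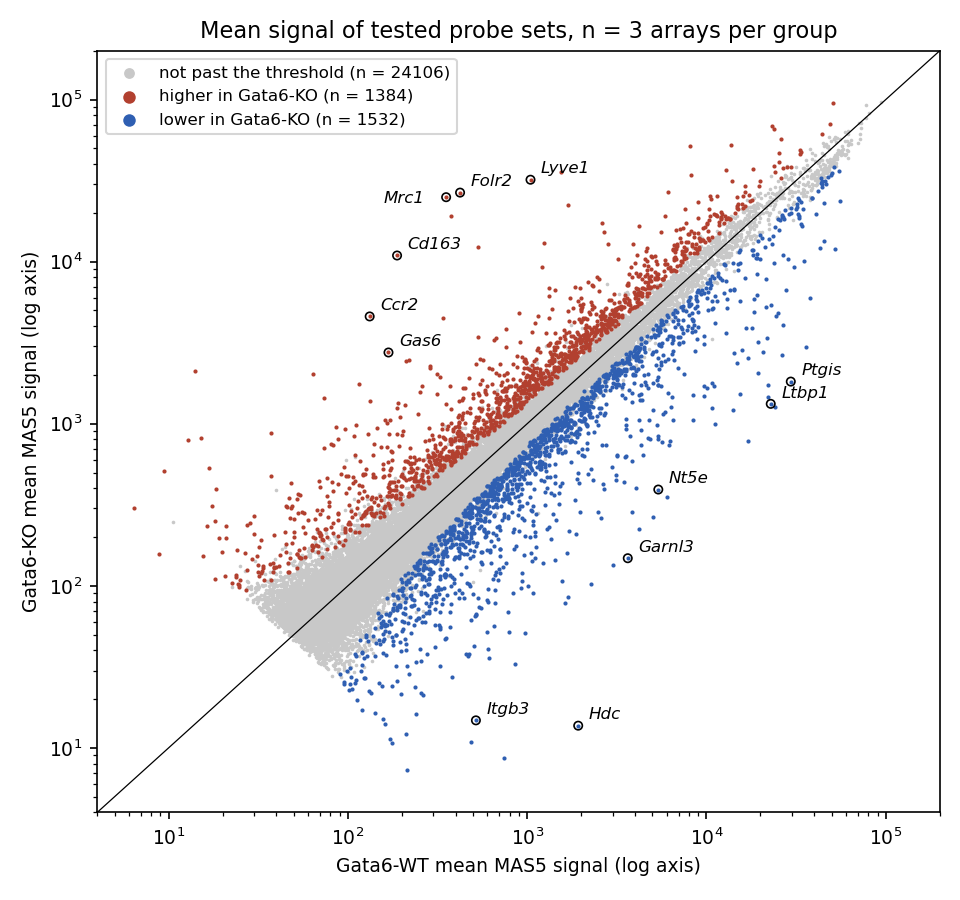
Mean MAS5 signal of each tested probe set in Gata6-WT (x axis) and Gata6-KO (y axis), both log axes, n = 3 arrays per group; red points are the 1384 probe sets higher and blue points the 1532 lower in Gata6-KO, and circles mark 12 named genes. Mrc1 lies at 353 in Gata6-WT and 24979 in Gata6-KO.

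The largest rises included the receptor genes Mrc1, Folr2, Cd163 and Lyve1. Mrc1, the mannose receptor, rose from 353 ± 131 to 24979 ± 1401 (71.0-fold, log2 6.15 ± 0.24, adjusted p = 3.8e-06), and Folr2, a folate receptor, from 423 ± 228 to 26663 ± 4804 (68.4-fold, adjusted p = 2.9e-05). Cd163, a scavenger receptor for haemoglobin complexes, rose 44.1-fold with a wide spread, at 8515, 4054 and 20168 in Gata6-KO replicates 1, 2 and 3 (log2 5.46, and 4.87 to 6.03 with 1 array left out). The hyaluronan receptor gene Lyve1 rose 29.7-fold. Ccr2, the receptor of the chemokine CCL2, rose 23.9-fold, with 9632 in Gata6-KO replicate 1 against 2400 and 1740 in the other Gata6-KO arrays; over its 4 tested probe sets the log2 difference ran from 1.08 to 4.58, with 3 past the threshold, and at the reported one from 3.84 to 5.07 with 1 array left out. Gas6, a ligand of the receptors MERTK and AXL, rose 15.1-fold at the probe set with the higher signal (log2 3.91), while its other probe set, at 0.79, did not pass (mean of both 2.35). The lysophosphatidylserine receptor gene Gpr34 rose 17.9-fold. The other genes of the 12 with the largest rise were Fxyd2 (27.9-fold), Cd209g (25.9-fold), the carbonyl reductase gene Cbr2 (23.4-fold), Pcolce2 (19.3-fold) and Tafa5 (13.9-fold; log2 3.79, and 3.21 to 4.39 with 1 array left out). Some of the 12 rises were larger in the male-type arrays and others smaller. Cd209g and Pcolce2 had log2 differences of 5.14 and 4.68 in the female-type arrays and 3.79 and 3.44 in the male-type arrays. Those of Lyve1, Fxyd2 and Gas6 were nearly equal in both. In the female-type arrays the log2 difference was 5.81 for Mrc1, 5.70 for Folr2 and 4.08 for Ccr2, and in the male-type arrays 6.83, 6.89 and 5.58. The limma interaction of sex and genotype had an adjusted p of 1.00 for each (unadjusted 0.0048, 0.0013 and 0.0039), and with 1 male-type array per genotype this shows neither a difference between the types nor its absence. Cd209g, Pcolce2, Gpr34, Tafa5 and Fxyd2 had wild type means of 64.3 or less, so their folds depend on the pseudocount (with 64 and with 1, Cd209g was 9.98-fold and 65.6-fold, and Tafa5 7.81-fold and 19.0-fold).

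The largest falls included enzymes of histamine, prostacyclin and adenosine production. Hdc, which makes histamine from histidine, fell from 1926 ± 386 to 13.7 ± 10.3 (log2 -6.08 ± 0.29, adjusted p = 8.4e-06). Ptgis, prostacyclin synthase, fell from 29529 ± 3018 to 1820 ± 1347 (19.7-fold), and Nt5e, the ecto-enzyme CD73 that forms adenosine, from 5388 ± 1102 to 393 ± 273 (log2 -4.00). Ltbp1, which binds latent TGF-beta, fell 23.6-fold from 22828 ± 3035, and Garnl3 31.7-fold. The tight junction gene Ocln fell 21.6-fold and the integrin subunit gene Itgb3 18.1-fold. The protease gene Ctse fell 19.3-fold at the probe set with the higher signal (log2 -4.27), while its other probe set, at 0.01, did not pass (mean of both -2.13). Pi16 (22.7-fold), Tmem263 (19.5-fold), Tox2 (18.2-fold) and Rprm (16.4-fold) completed the 12. The median of these 12 genes was 1.73% of the wild type mean in Gata6-KO replicate 1, 6.88% in replicate 2 and 5.48% in replicate 3. For 10 of the 12, all but Ctse and Itgb3, the lowest signal was in replicate 1. Over all 36 genes lowered at least 8-fold, replicate 1 was the lowest for 24. In the female-type arrays the log2 differences of Garnl3, Ltbp1, Pi16 and Nt5e were -3.85, -3.69, -3.68 and -3.17 and in the male-type arrays -7.26, -6.29, -6.15 and -5.67. Those of Tmem263 and Ptgis were -3.72 and -3.78 against -5.42 and -5.33. Ctse and Itgb3 differed little between the types, at -4.20 and -4.09 against -4.41 and -4.35. With 1 array left out Garnl3 ran from -5.66 to -3.95, Ltbp1 from -5.16 to -3.62, Pi16 from -4.84 to -3.91, Ptgis from -4.87 to -3.70 and Nt5e from -4.51 to -3.33. Low Gata6-KO signals made folds depend on the pseudocount: with 1 and with 64, Hdc fell 178.8-fold and 25.5-fold, Itgb3 40.7-fold and 7.36-fold, and Tmem263 32.6-fold and 9.64-fold.

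**Figure D2:**
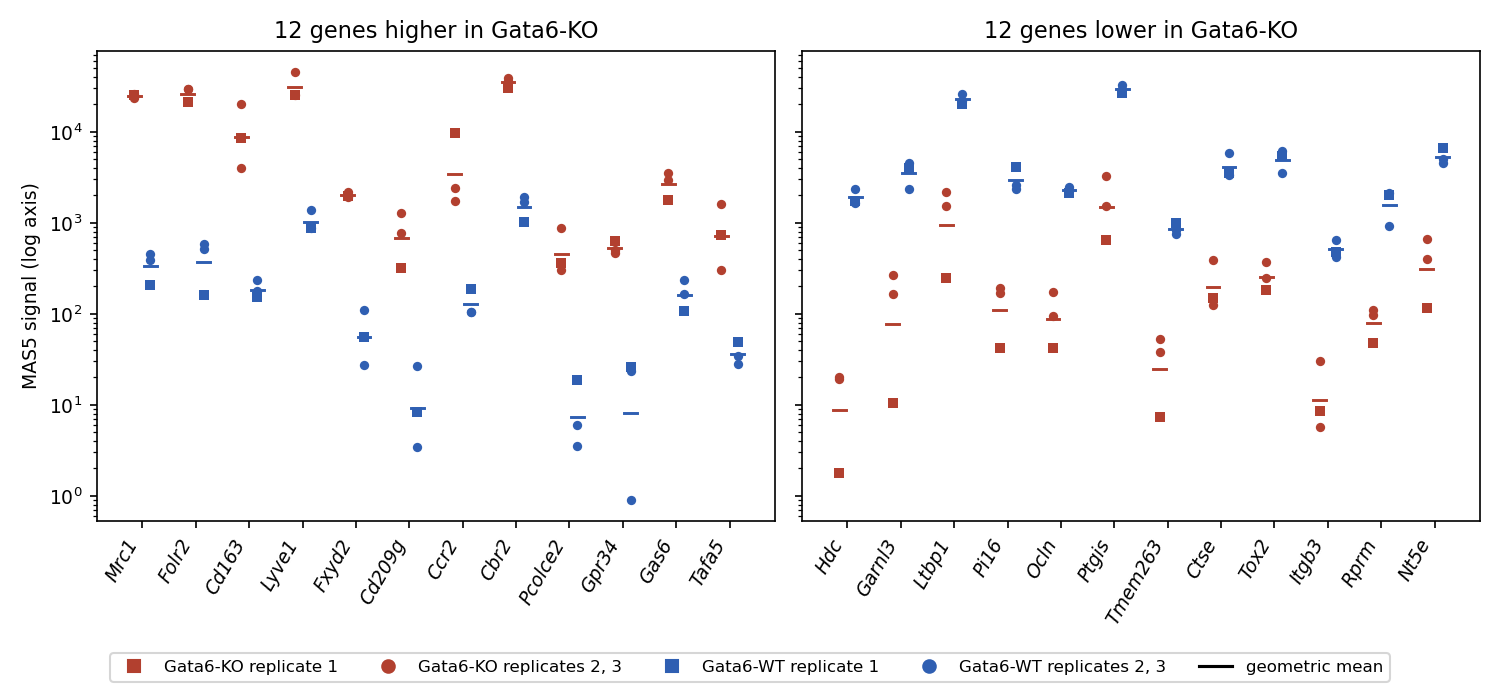
MAS5 signal (log axis) of the 12 genes with the largest rise and the 12 with the largest fall in each Gata6-KO and Gata6-WT array; squares are the replicates numbered 1, circles replicates 2 and 3, and bars geometric means of 3 arrays. The groups do not overlap for any of the 24 genes, and Ccr2 in Gata6-KO replicate 1 stands at 9632.

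Of 27 measured genes that characterise resident peritoneal macrophages, 19 fell and 2 rose (adjusted over the list alone, 22 and 2), with a median log2 difference of -2.01 (female-type -1.92, male-type -1.66). Camera gave an adjusted p of 1.4e-10 for the list, and adjusted p = 0.41 with an estimated correlation. Fabp4, a fatty acid binding protein, fell from 21958 ± 6753 to 1459 ± 591, the laminin-binding integrin Itga6 from 35680 ± 3144 to 2975 ± 1928, and Selp, P-selectin, from 26511 ± 1804 to 2665 ± 1018. Tgfb2 fell by 2.01, the coagulation factor gene F5 by 1.80 and Timd4, a phosphatidylserine receptor, by 0.70 on the log2 scale. The ficolin gene Fcna rose (log2 1.58, adjusted p = 7.0e-05), as did Hal, whose call was kept in 2 of 6 fits that each left out 1 array. Several members of this list are known as GATA6-linked from work that may include these samples, so it is not independent evidence of direction.

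Genes of general macrophage identity went both ways, with 7 of 21 higher, 3 lower and a median log2 of 0.20 (list alone, 8 and 3; female-type 0.17, male-type 0.25). Besides Mrc1 and Cd163, the scavenger receptor Marco rose from 1682 ± 304 to 22344 ± 8503 and the transcription factor Maf from 6098 ± 865 to 26932 ± 1099. Fcgr1, the high-affinity IgG receptor, fell from 1110 ± 270 to 148 ± 51.9, and Adgre1, which encodes F4/80, from 43123 ± 3980 to 12149 ± 3204. Camera gave an adjusted p of 0.022 for a shift up, and adjusted p = 0.41 with an estimated correlation. In the alternative activation list, which shares Mrc1 and Cd163 with the identity list, 7 of 14 members rose and 3 fell (list alone, 8 and 3), with a median of 0.87 (female-type 0.88, male-type 0.64). There Retnla rose from 12800 ± 6595 to 36951 ± 4885 and Clec10a 2.36-fold, while the lectin gene Mgl2 fell from 419 ± 14.7 to 83.8 ± 27.2. The adjusted p was 0.037, 0.41 with an estimated correlation and 0.073 without Gata6-KO replicate 2, with a range of 0.0029 to 0.074 over 19 variations of the fit.

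Of 12 measured genes of other tissue macrophages, 3 rose (Pparg, Hmox1 and P2ry12) and 3 fell (Fabp5, Runx3 and Cd5l), with adjusted p = 0.87. Pparg, a nuclear receptor of alveolar macrophages, was at 250 ± 183 against 18.1 ± 7.39, and Fabp5 fell from 17044 ± 4753 to 2555 ± 453. The median was 0.13, the mean -0.03, and fry pointed down. The list of monocyte and small peritoneal macrophage genes had 6 of 14 higher and 2 lower (adjusted p = 0.14; median 0.20, female-type -0.01, male-type 0.63). Folr2, Ccr2, the coagulation factor subunit F13a1 (8122 ± 2257 to 51961 ± 3970) and Chil3 had the largest rises in it, and Vcan fell from 383 ± 76.4 to 27.6 ± 16.8. The Chil3 call was lost without Gata6-KO replicate 1.

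Of 24 adhesion molecules 11 fell, 0 rose and 13 did not pass (list alone, 11 lower and 1 higher; median -0.47, female-type -0.46, male-type -0.48). The camera adjusted p was 0.00069, and adjusted p = 0.41 with an estimated correlation. Icam2, Itga6, Selp and Cd9, all lower, are also members of the resident peritoneal macrophage list, so the calls of both lists are not independent. Itgb3, Itga6 and Selp were joined by the tetraspanins Cd81, from 10734 ± 694 to 1254 ± 695, and Cd9, from 24986 ± 2830 to 4854 ± 1608. The integrin subunit gene Itgb7 fell by 1.83 and Itgb1 by 1.03 on the log2 scale. Genes for clearance of apoptotic cells divided into 5 higher and 5 lower of 19 (list alone, 7 and 5; adjusted p = 0.82). Gas6 and the UDP receptor P2ry6 rose, P2ry6 from 212 ± 37.7 to 2446 ± 309, whereas Itgb3 and Mfge8, a bridge between phosphatidylserine and integrins, fell, Mfge8 from 2282 ± 265 to 523 ± 83.8.

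Lipid genes changed in both directions, with 6 of 25 higher and 6 lower in the list of uptake, storage and efflux (list alone, 8 and 6; adjusted p = 0.71; the median was 0.07, the mean -0.10, and fry pointed down). Fabp4, Fabp5 and Apoc1 fell, as did Lpl, lipoprotein lipase, from 40777 ± 1063 to 19542 ± 997. The cholesterol exporters Abca1 and Abcg1 rose, Abca1 from 7550 ± 1468 to 21020 ± 2189, and so did Mylip and Pltp. Of 19 cholesterol biosynthesis genes 3 fell, among them Fdft1 and Idi1, and 1 rose (list alone, 5 lower and 1 higher; adjusted p = 0.074, with a range of 0.0093 to 0.17 over 19 variations of the fit, 5 of them past the threshold). In eicosanoid synthesis, 3 of 14 rose and 2 fell (list alone, 4 and 3; adjusted p = 0.59; the median and the test were above 0 and the mean -0.14). Thromboxane synthase, Tbxas1, rose from 2009 ± 478 to 6007 ± 328 and Ptgr1 from 1980 ± 239 to 5402 ± 798, while Ptgis fell and Alox15 fell from 55269 ± 9013 to 23690 ± 4067.

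Among cell cycle regulators of G1, 5 of 22 members fell and 0 rose (list alone, 6 and 1; adjusted p = 0.13), namely the cyclins Ccnd1 and Ccnd3 and the inhibitors Cdkn1c, Cdkn2b and Cdkn2c. Ccnd3 fell from 2559 ± 278 to 1171 ± 80.3 and Cdkn2b from 1192 ± 109 to 447 ± 147. In S phase 1 of 23 genes passed, the licensing factor Cdt1 at log2 -0.95, with a median of -0.34 (female-type -0.37, male-type -0.31) and an adjusted p of 0.042. That call had adjusted p = 0.83 with an estimated correlation, and was lost without Gata6-KO replicate 2 (0.073), Gata6-KO replicate 3 (0.078), Gata6-WT replicate 1 (0.084) or Gata6-WT replicate 3 (0.42), with a range of 0.00034 to 0.42 over 19 variations of the fit, of which 7 kept the call. Among those that lost it were the replicate block (0.060) and the sex-linked term (0.054). In 3 of the 9 other splits of the 6 arrays into 3 and 3 the adjusted p was as low. In G2 and M phase 1 of 24 passed, Kif23 at log2 1.27 (list alone, 0), with adjusted p = 0.42 for the list.

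In the TGF-beta list 5 of 22 fell and 1 rose (list alone, 5 and 3, camera adjusted p = 0.20), and its members Id2 and Id1 fell by 3.48 and 3.13 on the log2 scale, Id2 from 14147 ± 4250 to 1219 ± 144. Retinoid genes had 3 of 14 lower and 0 higher (adjusted p = 0.59), led by Cyp26a1, which degrades retinoic acid, from 969 ± 141 to 51.3 ± 32.5, with Rarg and Rarb at log2 -0.68 and -0.59. Of 6 measured GATA family genes and partners, Gata6 was the 1 that passed (adjusted p = 0.92; the median lay just above 0 and the mean just below). Type I interferon response genes had 2 of 18 higher, Rsad2 (138 ± 41.2 to 467 ± 178) and Oas1a (log2 0.66), with a median of 0.36 (female-type 0.33, male-type 0.31) and an adjusted p of 0.023. It was 0.79 with an estimated correlation, and the call was lost without Gata6-KO replicate 2 (0.16), Gata6-WT replicate 1 (0.074) or Gata6-WT replicate 3 (0.061), with a range of 0.00092 to 0.16 over 19 variations. In 2 of the 9 other splits of the arrays the adjusted p was as low. Inflammatory and NF-kB genes had 1 of 16 higher, Cd40, and 1 lower, Socs3 (list alone, 2 and 3; adjusted p = 0.92; median 0.08, mean -0.10). In complement and coagulation 2 of 21 rose, Gas6 and F13a1, and 3 fell, Thbs1, F5 and Pros1 (list alone, 6 higher and 5 lower; adjusted p = 0.77; fry pointed down with a median of 0.11).

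Genes of MHC class II presentation, the marker on which the cells were gated low, had 2 of 11 higher, H2-Ab1 from 419 ± 108 to 1030 ± 442 and Cd74 from 305 ± 56.2 to 638 ± 137 (adjusted p = 0.14). Lysosome and phagosome genes had 6 of 23 higher and 3 lower (list alone, 9 and 3; adjusted p = 0.14), with the proton pump subunit Atp6v0d2 rising from 45.7 ± 12.7 to 308 ± 42.0 and Glb1, beta-galactosidase, falling from 5545 ± 1624 to 1702 ± 559. In apoptosis and survival 1 of 16 rose, Casp8, and 3 fell, Aspa, Pmaip1 and Birc2 (list alone, 2 and 3; adjusted p = 0.72). In glycolysis Pfkfb3 rose by 1.52 on the log2 scale and Aldoc, Slc2a1 and Hk2 fell, out of 17 (list alone, 3 higher and 4 lower, camera adjusted p = 0.71). Oxidative phosphorylation had 3 of 24 higher and 2 lower, with Cycs at log2 0.75 and Cox5a at 0.72 (adjusted p = 0.68; median -0.03, mean 0.02). In the list of dissociation and stress genes 4 of 19 fell, Egr1, Zfp36, Ier2 and Junb, and Hsp90aa1 rose (adjusted p = 0.59).

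Of 41 measured markers of 8 cell types other than monocytes and macrophages, 1 was higher and 7 were lower. B cell genes had 0 of 9 higher and 1 lower, Bank1 (adjusted p = 0.87), dendritic cell genes 0 of 9 higher and 2 lower, Cd24a and Cd209a (0.32), and mesothelial and stromal genes 0 of 5 past the threshold (0.63), with Krt8 at log2 0.45. Neutrophil genes had Mmp9 higher and S100a8 and Csf3r lower out of 6 (list alone, 1 and 3; 0.45). Mast cell and basophil genes had 1 of 5 lower, Hdc (list alone, 3 lower), with an adjusted p of 0.064 that ranged from 0.021 to 0.20 over 18 variations of the fit, 5 of them past the threshold. The T and NK cell (4 measured), eosinophil (2), erythroid (1) and sex-linked (4) lists were too small to test. Cd8a, Il7r and Gzma had log2 differences of -0.64, -0.48 and 0.46 and Klf1 0.64, none past the threshold (Klf1, the 1 erythroid gene measured, passed when adjusted over its list alone), and Alox15 was the 1 eosinophil gene that fell.

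**Figure D3:**
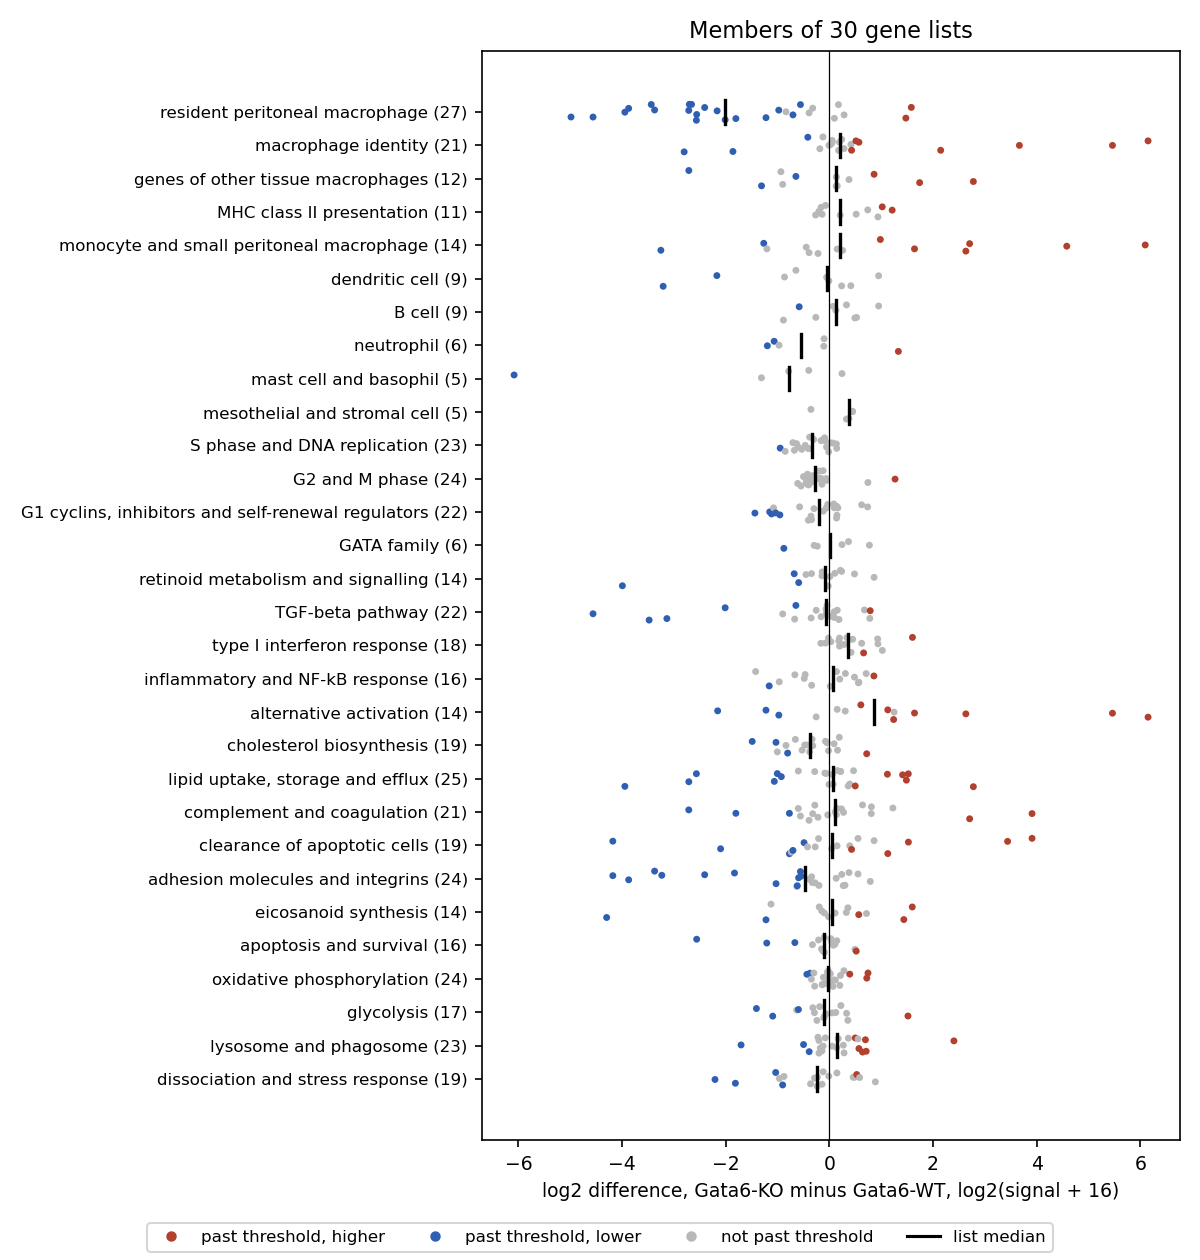
Log2 difference (Gata6-KO minus Gata6-WT, on the log2(signal + 16) scale, x axis) of each measured gene in the 30 tested lists (y axis, number measured in brackets); red and blue points passed the threshold as higher and lower, grey points did not, and black bars are list medians. The resident peritoneal macrophage list has its median at -2.01 and the alternative activation list at 0.87.

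Over the 30 tested lists camera called 6, of which 0 held after adjustment with an estimated correlation. Before adjustment 2 lists had a camera p under 0.05 there, adhesion molecules (0.021) and alternative activation (0.044). The unadjusted camera p was 0.060 for the resident peritoneal macrophage list and 0.068 for macrophage identity. It was 0.29 for the interferon response and 0.44 for S phase. Fry called 12 lists as moving on balance one way and 25 as changing in either direction, without comparison to other genes. The log2 ratio of 3' to 5' control signal was 0.50 ± 0.030 in Gata6-KO and 0.55 ± 0.033 in Gata6-WT for Actb, and -0.50 ± 0.025 and -0.40 ± 0.034 for Gapdh, with the groups apart in both (exact permutation p = 0.1, the smallest possible). Of the 145 calls of named and listed genes, 100 held in each fit that left out 1 array and 45 were lost in at least 1 such fit. Among genes named above the latter were Icam2 (kept in 1 of 6 fits), Hal, Chil3, Cd5l, P2ry12, H2-Ab1, Bank1, Mmp9, S100a8, Kif23, Rarg, Rarb, Rsad2, Oas1a, Cd40, Birc2, Aldoc, Slc2a1, Hk2, Egr1, Zfp36, Junb and Hsp90aa1. Of 63 listed or named genes past the threshold with several tested probe sets, 24 had another that did not pass, among them Ccnd1, Ccnd3, Fdft1 (-1.49 at the reported one, 0.79 at another), H2-Ab1, Hsp90aa1, Itgb1, Mmp9, Pfkfb3, Rarg and Vcan.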

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

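In none of the 20 other fits did a probe set called in both that fit and the reported one change direction. Of 3235 values for 155 named genes under the alternatives, 2707 kept direction and side of the threshold, 517 lost the threshold and 11, for sex-linked genes not past it, changed sign. All 500 values of the 24 genes with the largest changes were kept. Those 24 were chosen from the same arrays for large changes and non-overlapping groups, which made this outcome likely in advance. Of 654 values for the 30 gene lists, 554 kept direction and side of the threshold, 30 lost it, 44 gained it and 26, for lists not past it, changed direction. The changed probe sets numbered 1459 without the variance trend (655 higher, 804 lower), 1251 at adjusted p under 0.01 (582, 669), 1256 at 2-fold (553, 703) and 527 with treat against 1.5-fold (217, 310), the last 3 by construction. The female-type arrays alone, a fit chosen after the data were seen, gave 1654 (787, 867) with fewer samples. Leaving out 1 array gave 1856 to 2476 in all, 822 to 1240 higher and 939 to 1236 lower. The highest-signal Gata6 probe set stayed at -0.88 but passed neither without the trend (adjusted p = 0.067; range over its alternatives 0.0039 to 1.00) nor the stricter thresholds, and the lowest-signal one at -1.15 did not pass treat. The intermediate one, never past the threshold, was 0.0454 with median scaling, 0.0746 with array weights, and -0.17 to 0.18 with 1 array left out. The number of gene lists called was 2 at adjusted p under 0.01, 0 with an estimated correlation, 12 with fry directional, 25 with fry mixed, and 3 (without Gata6-KO replicate 2) to 8 with 1 array left out; where construction does not show it, the cause was not tested. With the replicate block the fit called 3076 probe sets and 5 lists. Of the 145 calls of named and listed genes, 7 were lost with that block and 6 with the sex-linked term. Same-numbered arrays had deviation correlations of 0.13, 0.07 and 0.07, and across genotypes each array correlated best with its own number. The second principal component, with 16.2% of the variance, also followed the numbers. Its scores were 31.8, -10.6 and -27.9 in Gata6-KO replicates 1, 2 and 3 and 36.7, 8.73 and -38.7 in Gata6-WT. The labels do not say that the numbers mark a shared day, litter or sort, so they were not taken as pairs. A factor shared by same-numbered arrays stays open. Signals near background limit folds: that of Hdc ran from 25.5 to 178.8 with the pseudocount.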

Other observations

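The gene families in this paragraph were chosen by symbol after their values were seen, and no camera test of the 4 large enough passed (lowest adjusted p = 0.10, for CC chemokines and receptors). Genes taken by symbol as C-type lectins, not all of them receptors, divided into 6 higher and 6 lower of 26: Cd209f rose from between 93.0 and 138.2 to between 1087 and 2452, Clec4a2 and Clec2d rose by 2.54 and 1.77 on the log2 scale, and Cd209b and Clec1b had log2 differences of -2.59 and -2.63. Tetraspanins had 5 of 22 lower, with Tspan13 at -3.33 beside Cd81 and Cd9, and 3 higher. Among purinergic and adenosine genes 4 of 19 rose and 3 fell: P2rx1 and P2ry14 were at -2.47 and -2.20, while adenosine deaminase, Ada, was at 1.69 and P2ry6 at 3.44. Of 4 Fc gamma receptor genes, Fcgr1 and Fcgr4 were lower (-2.80 and -1.57) and Fcgr2b higher (0.80). The CC chemokines Ccl6, Ccl9 and Ccl24 were higher, Ccl6 at 1.14. In the 6 fits that each left out 1 array, Fcgr2b, Ccl24, P2ry12 and Tspan3 kept their calls in 2, P2rx4, Clec4g and Tspan14 in 1 and Tspan32 in 4, so none of the 3 tetraspanin rises held in all 6.

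The tests below were chosen after the results they bear on were seen, except the comparison with unchanged genes, the list of LYVE1-positive macrophage genes and the splits of the arrays. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The genotype split called 2916 probe sets, 1 of 10 splits with as many, and the highest other split called 1. Each other split put arrays of both genotypes in both groups. The genotype difference then widened the spread within groups, which fixed in advance that few probe sets would be called there. That comparison is therefore no measure of chance. Those splits also held the genotypes in unequal shares, so a list that differs by genotype can pass in them. For the gene lists, 2 of 10 splits called as many, the genotype split with 6 and another with 7. In single lists, 3 other splits had an adjusted p as low as the genotype split for S phase and 2 for the interferon response, and 0 for the other 4 called lists, although the resident peritoneal macrophage list passed in 4 other splits.

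Residual expression of lowered genes differed between the Gata6-KO pools: over the 36 genes lowered at least 8-fold, the median was 3.53% of the wild type mean in replicate 1, 9.12% in replicate 2 and 8.36% in replicate 3. Array scaling or background is argued against by unchanged genes of the same signal, whose median log2 ratio of replicate 1 to replicates 2 and 3 was 0.0635 where the 36 genes had -0.95. A sex difference shared by both genotypes is argued against by the wild type pools, where the 36 genes had a median of 0.13. Undeleted cells in replicates 2 and 3 may contribute. Gata6 itself kept the most signal in replicate 1 at each of its 3 probe sets. At the lowest-signal one the pools were nearly equal, with 43.5%, 40.8% and 43.3% in replicates 1, 2 and 3. Its probe sets may also lie outside the deleted part, so Gata6 cannot decide this. A single share of such cells would add the same percentage to each gene. The gain of replicate 2 over replicate 1 ran from -5.50 to 19.5 points, with a lower quartile of 0.54 and a median of 5.05. Undeleted cells therefore cannot be told apart from differences between pools. This measure of the gain replaced a first version, which argued against undeleted cells, after that value was seen. A response to Gata6 loss that depends on sex stays open. With 1 male-type pool per genotype and few residual degrees of freedom, a fit of the interaction of sex and genotype cannot decide it.

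Gata6 signal remained in the Gata6-KO pools, at 40.8% or more of the wild type mean. Undeleted cells as the whole source would hold every gene at that share, and are argued against by all 6255 genes with wild type signal above the median: 200 to 230 of them lay below 40.8% in each Gata6-KO pool, where 11 to 14 did in a wild type array set against the other wild type arrays. This count replaced a measure over genes selected for their fall, whose outcome the selection had fixed. Probe sets outside the deleted part of the gene are a candidate explanation, as the log2 differences of the 3 probe sets span 1.14, but probe positions and the deleted part are unknown here, so this stays open.

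Receptor genes such as Mrc1, Folr2, Cd163 and Lyve1 were far higher in Gata6-KO. Of 41 measured markers of lymphoid, dendritic, granulocyte, mast, mesothelial and erythroid cells, 2.44%, 1 gene, were higher. This argues against B cells, dendritic cells, neutrophils, mast cells and mesothelial cells as the source of the rises. The count covers only markers higher in Gata6-KO, so it cannot show cells present in both groups or mainly in wild type pools. Mast cell and basophil genes, Hdc among them, had a median log2 difference of -0.78, and mast cells in the wild type pools were not tested. The count also cannot decide for T and NK cells, eosinophils or erythroid cells, with 4 of 17, 2 of 10 and 1 of 9 listed markers measured. Monocytes or small peritoneal macrophages stay open, since 42.9% of 14 measured genes of their list were higher, Folr2, Ccr2 and F13a1 among them, and Vcan and Clec4e lower. Folr2 is itself among the receptor genes to be explained, so it adds no separate evidence. A sort for high CD11b and low MHC class II selects against small peritoneal macrophages. In pooled RNA monocytes or small peritoneal macrophages cannot be told apart from altered expression in the same cells. A hypothesis is that the gate holds more of the gene programme of LYVE1-positive tissue macrophages, and a list of 18 further genes was written before its values were seen. Of these 8 were higher (Wwp1 at log2 1.39, Sesn1 at 0.89) and 3 lower (Igf1 at -2.59, Cd209b and Fgfr1). In the 6 fits that each left out 1 array, Selenop kept its rise in 2, Colec12 in 3 and Fcgrt in 5, while the 3 falls held in all 6. The camera p of 0.040 met the criterion set beforehand, but p = 0.30 with an estimated correlation, a requirement added afterwards, and a mean of 0.02 against a median of 0.54 leave the hypothesis undecided.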
